A study of Mus musculus with 6 samples.

How the data were processed

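RNA from mouse liver was sequenced in 3 wild-type and 3 Hbp1 knockout libraries, prepared with a kit that isolates mRNA, per the labels' protocols. Reads were aligned with HISAT2 to the mm10 build, per the submitters' processing notes; the tool that estimated expression and the gene annotation are not given in the sources used here. The authors deposited 1 table per library with an FPKM value per gene, and per the file headers these are FPKM with gene loci; no counts were used. Neither the read depth nor counting intervals can be given from FPKM. No value in the files was 0, and 20164 genes were listed in at least 1 library and 13939 in all 6. A gene that a file does not list was entered as 0, which may be a failed estimate, since 209 genes above 1 FPKM in some library were unlisted in another.

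Samples were grouped by genotype as in the titles. The choices of test, filter, gene lists, named genes and most alternatives were made before the data were examined. Values were taken as deposited, without further scaling, as log2(FPKM + 1), so log2 differences understate the change of low genes. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested (9748), with Hbp1 and Igfbp1 included whatever their level. The test was limma 3.58.1 in R 4.3.3, with genotype as the only factor and a variance prior that follows mean expression, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Exact two-sided permutation tests were made for Hbp1 and Igfbp1.

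Lists of genes (50 lists with 1067 entries, of pathways, known regulated sets and cell-type markers) were fixed in advance, and 1033 entries were found in the files. The 43 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation, on ranks, and with fry. The directional fry test asks whether a list moves one way and does not compare it with other genes. None was called with an estimated correlation, where the lowest adjusted p was 0.30 and 6 lists had an unadjusted p under 0.05, and none by the directional fry test, while 11 were called by its mixed test. Named genes were Hbp1 and Igfbp1, the 10 largest rises and falls among genes past the threshold whose groups did not overlap (unnamed models, Rik, -ps and numbered -rs genes left out). They were also up to 4 members with the smallest p from each called list and from the IGF, insulin, gluconeogenesis, glycolysis, lipogenesis, HBP1 and cell cycle lists, and the 3 most abundant members of called cell-type lists. Serpina1e, the clock, metallothionein and Scd1 genes and the near-identical copies fall outside this rule and were chosen after their values were seen.

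On simulated data with 200 of 9748 genes changed in the knockout against wild-type comparison, the test recovered 39.2% of changes of 1 and 98.2% of changes of 2 on the log2 scale, and 6.39% of its calls were false. In the same simulation, camera called the shifted list in 5 of 5 runs and 0 of 210 unshifted lists, but simulated genes varied independently, unlike those of the libraries.

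Gene coordinates, transcript lengths, GC content and near-identical copies came from GENCODE release M21 on the mm10 assembly. Copies were transcripts that BLAST 2.17.0 aligned at 95% identity or more over at least 50% of the shorter one, and 1214 tested genes had one. Genes overlapping at the same locus were not excluded, and 7615 genes shared a locus in the files with another gene. Some copies may therefore be neighbours that share sequence, as Ncaph2 and Sco2 may be for Tymp. Alternatives changed the pseudocount, filter, scaling, variance model, replicate number as a block, the set of libraries and the set test. Those chosen after seeing the data were a term for wild-type 1 and knockout 2, leaving both out, correction for GC content and length, Dbp as a covariate, copies summed, and only genes listed in all 6 files. Count-based tests were not run because whole reads could not be recovered.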

Results

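Gene expression was measured by RNA sequencing of mouse liver of the C57BL/6 strain, in 3 libraries from wild-type liver and 3 from liver with a knockout of Hbp1, which encodes an HMG-box transcription factor. The libraries are named here by genotype and replicate, as wild-type 1 to 3 and knockout 1 to 3. The values were FPKM per gene, a level corrected for transcript length and for the number of mapped fragments. The files listed between 16047 genes (wild-type 1) and 16905 genes (wild-type 2), and the FPKM of a library summed to between 580611 and 641818. The read depth of the libraries is unknown, because FPKM does not hold it and whole reads could not be recovered from the low values. The labels do not say that the libraries of a genotype came from separate animals. The p-values therefore measure the spread between these samples, which may be technical. Sex, age, diet and time of collection are also not given by the labels. Effects of diet or collection time therefore cannot be told apart from genotype.

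The only comparison in the design was knockout against wild-type liver, and the series title names Igfbp1, which encodes a secreted binding protein for insulin-like growth factors, as a gene that HBP1 activates in the setting of type 2 diabetes. Knockout livers had lower levels of Hbp1 itself, of macrophage and antigen-presentation genes such as Cd5l, Csf1r, Cd74 and H2-Ab1, and of some male-biased liver genes such as Cyp7b1 and Selenbp2. They had higher levels of the fatty acid hydroxylase genes Cyp4a14 and Cyp4a10, of Angptl8, of Apoc2 and of the zinc transporter gene Slc39a5. The mean FPKM of Cyp4a14 was 98.8 ± 45.1 against 3.68 ± 2.30 (SD, n = 3), and that of Slc39a5 24.7 ± 13.1 against 0.528 ± 0.262. Igfbp1 was lower in every knockout library than in every wild-type library, but it missed the threshold of the test.

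Hbp1 (ENSMUSG00000002996, mm10 chromosome 12, 31926254 to 31950535, minus strand, protein-coding) had an FPKM of 15.4, 21.8 and 18.5 in wild-type 1 to 3 and of 2.85, 2.51 and 2.86 in knockout 1 to 3. It fell by 2.38 ± 0.235 (SE, n = 3 per genotype) on the log2(FPKM + 1) scale, with a limma adjusted p of 0.00223, and each knockout library lay below each wild-type library. These are values of the whole gene and do not show which exons remained in the knockout. The design text calls the altered samples KD, while the genotype and title labels say KO; the labels' knockout is used as the name here, and the remaining Hbp1 level does not settle which it was. The 3' part of Hbp1 overlaps the 3' end of Cog5 (31654869 to 31937630, plus strand). The sources do not state whether counting used the strand, so the Hbp1 level is uncertain to the extent of shared reads. The FPKM of Cog5 was between 0.168 and 0.868 in the 6 libraries.

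Igfbp1 (ENSMUSG00000020429, mm10 chromosome 11, 7197782 to 7202546, plus strand, protein-coding) had an FPKM of 53.01, 286 and 403 in wild-type 1 to 3 and of 8.13, 38.6 and 19.2 in knockout 1 to 3. The difference was -3.25 ± 0.723 on the log2 scale, with a 95% interval from -4.86 to -1.63, and the limma adjusted p was 0.0672 over the 9748 genes tested. An exact two-sided permutation test of either gene gave p = 0.10, the smallest that 3 libraries against 3 allow. Igfbp1 passed the threshold without wild-type 1 (-4.13, adjusted p = 0.0159). It passed in no fit that left out another single library, where the adjusted p lay between 0.106 and 0.245. Over all 25 alternatives the adjusted p ranged from 0.000648 to 0.35, and Igfbp1 passed in 6. Those with all 6 libraries were array weights, the replicate block, the term for wild-type 1 and knockout 2, and Dbp as a covariate. Within the pair of knockout 2 and wild-type 1 the difference was -0.447, and between the other 4 libraries it was -4.65.

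**Figure D1:**
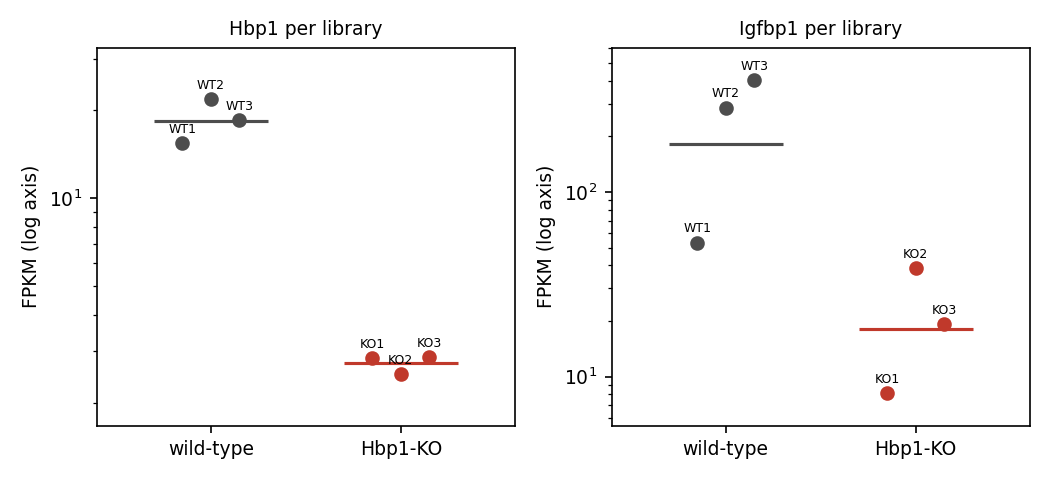
FPKM of Hbp1 and Igfbp1 in each of the 6 libraries, on log axes, with a line at the geometric mean of each genotype. The knockout libraries lie below every wild-type library for both genes, and wild-type 1 has the lowest Igfbp1 of its group (53.01).

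Over all genes, 138 of 9748 passed the threshold, 37 higher and 101 lower in the knockout, and 132 of them differed by at least 1 on the log2 scale. The groups did not overlap for 1299 genes (13.33%), against 10% by chance, and this held for each of the 138 genes. Among named genes past the threshold, the largest rises were those of Cyp4a14 (log2 difference 4.44 ± 0.411, adjusted p = 0.00171), which encodes a microsomal fatty acid omega-hydroxylase, and of Slc39a5 (3.97 ± 0.353, adjusted p = 0.00170). The largest falls were those of Mup7 (-4.04 ± 0.284, adjusted p = 0.000585), a major urinary protein gene, and of Mup15 (-3.25 ± 0.333, adjusted p = 0.00250). Both belong to a family of near-identical copies, and with the copies summed the difference was -1.42 ± 0.376 and missed the threshold (adjusted p = 0.13). The number of genes past the threshold was 28 without knockout 3, 39 without wild-type 2, 40 without wild-type 3 and 42 without knockout 2. Of 38 named genes past the threshold, 34 missed it with no filter on low values, where 8 genes passed in all, and 23 with the replicate number as a block, where 24 passed.

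Markers of Kupffer cells, the resident macrophages of the liver, were lower in the knockout. Of 17 markers tested, 9 fell after adjustment over all genes tested and 16 adjusted over the list alone, the median log2 difference was -1.98, and all 17 were below 0. Cd5l, a scavenger receptor family protein of tissue macrophages, had a mean FPKM of 129.8 ± 10.4 (SD, n = 3) in wild-type and of 23.1 ± 4.60 in knockout liver. Csf1r, the receptor for the growth factor of macrophages, fell by 2.24 ± 0.297 (adjusted p = 0.00730), and Cd68 by 2.19 ± 0.338 (adjusted p = 0.0168). Adgre1 (which encodes F4/80) fell by 1.98 ± 0.317 (adjusted p = 0.0190), and the complement genes C1qa and C1qb by 2.13 and 2.27. With 1 library left out, Cd5l and Csf1r passed in all 6 fits. Cd68 missed in 3 fits (without wild-type 2, wild-type 3 or knockout 2, adjusted p from 0.051 to 0.0737). Adgre1 missed in 4 (either of those wild-type libraries or knockout 2 or 3, 0.053 to 0.0832), and C1qa and C1qb in 4 (any wild-type library or knockout 3, 0.0531 to 0.111). The list was called by camera (adjusted p = 1.34e-25) but not with the correlation estimated from the data (adjusted p = 0.30 with an estimated correlation).

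Genes of antigen presentation on MHC class II fell together. All 7 of those tested fell, over all genes and adjusted over the list alone, with a median of -2.98. Cd74, the invariant chain, went from a mean FPKM of 323.7 ± 149.9 (SD, n = 3) to 34.9 ± 14.0, and H2-Ab1 from 145.4 ± 64.6 to 15.6 ± 6.59. H2-Eb1 and H2-Aa fell by 3.03 ± 0.443 and 2.98 ± 0.447 on the log2 scale. The peptide-loading genes H2-DMb1 (-2.31, adjusted p = 0.00411) and H2-DMa (-2.09, adjusted p = 0.00662) were also lower, and both passed with any 1 library left out. Without knockout 2, Cd74 (adjusted p = 0.0702), H2-Ab1 (0.0679), H2-Eb1 (0.075) and H2-Aa (0.0786) missed the threshold. H2-Eb1 and H2-Aa also missed it without knockout 3 (0.0517 and 0.0578), and H2-Aa without wild-type 2 (0.0528). The camera adjusted p was 2.10e-17 (adjusted p = 0.30 with an estimated correlation). Over the 24 genes of these 2 lists, the median difference was -2.03 between knockout 2 and wild-type 1, with 23 of 24 lower, and -2.10 between the other 4 libraries, with all 24 lower.

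Other immune lists were called in the same direction. Of 26 interferon response genes, 3 fell (Oas1g, Oas1a, Ifi47, the last an interferon-induced GTPase), and 15 adjusted over the list alone (median -0.78, camera adjusted p = 2.47e-13; adjusted p = 0.324 with an estimated correlation). With 1 library left out, Oas1a missed the threshold in all 6 fits (adjusted p from 0.0715 to 0.204). Ifi47 missed it in 4 (without wild-type 2 or 3 or knockout 2 or 3, 0.0963 to 0.177). Oas1g missed it in all 3 fits that tested it (without any one knockout library, 0.0839 to 0.0952). Without any one wild-type library, Oas1g was under the filter on low values and was not tested. None of 7 cytokine and chemokine genes passed over all genes, and 5 did adjusted over the list alone (camera adjusted p = 2.58e-05; adjusted p = 0.445 with an estimated correlation). Among them, Il1b had an FPKM of 6.39 ± 3.95 (SD, n = 3) against 0.567 ± 0.316. The list median of -1.37 was -0.70 without wild-type 3 (adjusted p = 0.017), -0.39 with no filter on low values and -0.72 with an FPKM of at least 0.1 in 3 libraries. No B cell or plasma cell gene passed over all genes or adjusted over the list alone (0 of 7), although camera called the list (adjusted p = 0.000894; adjusted p = 0.591 with an estimated correlation). Igkc was at 12.0, 200 and 298 in wild-type 1 to 3 and between 20.4 and 24.9 in the knockout. The call was lost without knockout 2 (adjusted p = 0.144) and with Dbp, a clock output gene, as a covariate (median -0.90 in place of -1.91, adjusted p = 0.0877). The median was -3.17 without wild-type 1, -1.09 without wild-type 3, -0.38 with no filter, -0.42 with an FPKM of at least 0.1 in 3 libraries and -2.89 with array weights. The list turned in direction within the pair of knockout 2 and wild-type 1 (median 0.68, against -3.10 between the other 4 libraries). Of 17 endothelial markers only Cdh5 (VE-cadherin) fell (-1.05, adjusted p = 0.0466), and 3 fell adjusted over the list alone (camera adjusted p = 2.20e-06; adjusted p = 0.468 with an estimated correlation). Cdh5 missed the threshold in all 6 fits with 1 library left out (adjusted p from 0.075 to 0.232), and the list median of -0.55 was -0.34 without wild-type 1. Only 4 T and NK cell genes were tested, too few for a list test, and 4 fell adjusted over the list alone and none over all genes. Stellate cell and erythroid lists were not called (camera adjusted p = 0.792 and 0.177). Among 26 acute phase genes none passed over all genes and 6 did adjusted over the list alone (median -0.63, camera adjusted p = 9.28e-09; adjusted p = 0.445 with an estimated correlation). The medians within the pair of knockout 2 and wild-type 1 and between the other 4 libraries were -0.39 and -1.03 for interferon, -0.45 and -1.91 for cytokine, -0.52 and -0.73 for acute phase and -0.79 and -0.54 for endothelial genes. Oas1a and Oas1g are near-identical copies, so their single values are uncertain; their sum passed (-1.39, adjusted p = 0.0173). Saa2 had its highest FPKM in wild-type 3 (4369) and 291 or 339 in the other wild-type libraries.

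Lipid genes were higher in part. Of 26 fatty acid oxidation and PPAR alpha target genes, 3 rose over all genes, and 6 rose and 1 fell adjusted over the list alone. The 3 were Cyp4a14, Cyp4a10 (mean FPKM 14.5 ± 3.84 to 135.9 ± 75.2) and Acot3, a peroxisomal acyl-CoA thioesterase. Cyp4a10 has near-identical copies and passed again with their values summed (2.62, adjusted p = 0.00941). The list had a median of 0.31 (camera adjusted p = 1.53e-06; adjusted p = 0.445 with an estimated correlation). The list median was -0.03 without knockout 2, when the list kept its call (adjusted p = 0.0106), 0.12 with array weights, 0.13 with Dbp as a covariate and 0.10 without wild-type 1 and knockout 2 together; within the pair of knockout 2 and wild-type 1 it was 0.66, and between the other 4 libraries 0.11. Angptl8, a hormone-like inhibitor of lipoprotein lipase, rose from an FPKM of 33.7 ± 7.23 to 344.6 ± 205.5 (SD, n = 3; adjusted p = 0.00549). Apoc2, the cofactor of lipoprotein lipase, rose from 245.8 ± 49.8 to 1154 ± 109.0 (adjusted p = 0.00332). Apoc2 shares sequence with a near-identical gene, Gm44805, and it passed again when their values were summed (adjusted p = 0.00507). In the lipoprotein list only Apoc2 passed, over all genes and adjusted over the list alone (1 of 19; camera adjusted p = 0.0498; adjusted p = 0.468 with an estimated correlation). This call was lost under 16 of 25 alternatives, among them without wild-type 2 (adjusted p = 0.0994), wild-type 3 (0.0866) and knockout 2 (0.233). The median of 0.14 was 0.07 without wild-type 2, without knockout 2 or with Dbp as a covariate, 0.09 with quantile normalization, 0.22 without knockout 1 and 0.005 with array weights, which let libraries differ in variance. No gene of de novo lipogenesis passed over all genes and 1 of 19 did adjusted over the list alone (median 0.59, camera adjusted p = 0.000169; adjusted p = 0.658 with an estimated correlation). This call was lost without knockout 2 (median -0.13, adjusted p = 0.551), without wild-type 1 and knockout 2 together (0.113) and with Dbp as a covariate (median 0.12, adjusted p = 0.124). The median was 1.11 without knockout 1 and 0.26 with array weights. It was 1.85 within the pair of knockout 2 and wild-type 1 and 0.02 between the other 4 libraries. Fasn, fatty acid synthase, had an FPKM of 251 in knockout 2 and of 41.9 and 62.0 in knockout 1 and 3, against 17.6 to 38.1 in wild-type liver.

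Genes known to be higher in male than in female liver were lower in part. Of 18 tested, 4 fell, namely Cyp7b1 (an oxysterol hydroxylase), Selenbp2, Nat8 and Mup20, and 6 fell adjusted over the list alone (camera adjusted p = 7.32e-07; adjusted p = 0.30 with an estimated correlation). Selenbp2 went from an FPKM of 1447 ± 359.4 to 169 ± 38.3 (SD, n = 3) and Cyp7b1 from 179.9 ± 46.5 to 21.9 ± 13.6. With 1 library left out, Selenbp2 passed in all 6 fits, and Cyp7b1 missed only without knockout 2 (adjusted p = 0.0624). Nat8 missed in 3 fits (without wild-type 1, wild-type 2 or knockout 3, 0.056 to 0.0709) and Mup20 in 5 (all but wild-type 1, 0.075 to 0.209). Selenbp2 has a near-identical copy and passed again with their values summed (-2.08, adjusted p = 0.0118). Of 17 major urinary protein genes, which encode pheromone carriers, 7 fell and 10 fell adjusted over the list alone (camera adjusted p = 7.04e-15; adjusted p = 0.324 with an estimated correlation). Their transcripts are nearly identical and reads could be split between them, so single members are uncertain: summed over the family of Mup7, the difference was -1.42 ± 0.376, with an adjusted p of 0.13. The list median of -1.29 was -0.85 without knockout 2 or with array weights and -0.58 with copies summed, and the list kept its call. Of 12 female-biased genes, 2 rose, Acot3 and Cyp2b9 (not listed in wild-type 1), and 3 rose adjusted over the list alone (camera adjusted p = 0.000314; adjusted p = 0.30 with an estimated correlation). The call was lost without knockout 1 (adjusted p = 0.168), without knockout 3 (adjusted p = 0.379) and among genes with a mean FPKM of at least 5 (adjusted p = 0.51). The median of 0.39 was 0.20 without knockout 1, 0.14 without knockout 3, 0.16 with no filter, 0.23 with copies summed, 0.71 with array weights, 0.73 with Dbp as a covariate and 1.41 without wild-type 1 and knockout 2 together, and the male-biased median of -0.41 was -0.67 with Dbp. Without any one wild-type library, Acot3 passed and Cyp2b9 missed the threshold (adjusted p from 0.0528 to 0.0778). Without any one knockout library, both were under the filter on low values and were not tested. The medians within the pair of knockout 2 and wild-type 1 and between the other 4 libraries were -0.63 and -0.45 for male-biased, -1.80 and -0.99 for urinary protein and 0.53 and 0.92 for female-biased genes. Y-linked Ddx3y, Eif2s3y and Kdm5d were listed in all 6 libraries.

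Lists on glucose and insulin were not called. In the IGF axis list no gene passed over all genes, and Igfbp1 alone passed adjusted over the list alone (1 of 10, camera adjusted p = 0.984); the median of this list was 0.06 and its mean -0.24. None of 22 insulin signalling genes passed by either adjustment (camera adjusted p = 0.792), with Irs2, an insulin receptor substrate, at -1.19 ± 0.326 (adjusted p = 0.157). In gluconeogenesis, 0 of 13 passed over all genes and 1 adjusted over the list alone, G6pc (glucose-6-phosphatase), at an FPKM of 246.9 ± 82.5 against 70.6 ± 40.9 (SD, n = 3; adjusted p = 0.0767). In glycolysis Pkm, the pyruvate kinase of cells other than hepatocytes, fell by 1.49 ± 0.275 (adjusted p = 0.0332; 1 of 17 by both adjustments, camera adjusted p = 0.90). Pkm missed the threshold in 5 of 6 fits with 1 library left out, all but knockout 1 (adjusted p from 0.0516 to 0.166). Of 12 genes reported as regulated by HBP1, none passed over all genes and 2 passed adjusted over the list alone (camera adjusted p = 0.133). Of 18 cell cycle genes none passed over all genes and 1, Tk1, passed adjusted over the list alone, at 1.11 ± 0.264 (camera adjusted p = 0.0663).

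The remaining called lists had few or no single genes past the threshold. None of 68 nuclear oxidative phosphorylation genes passed by either adjustment (median 0.24, camera adjusted p = 1.53e-06; adjusted p = 0.468 with an estimated correlation). Without wild-type 1 this median was 0.11 (adjusted p = 0.00334). Nor did any of 75 ribosomal protein genes (median 0.20, camera adjusted p = 0.000211; adjusted p = 0.716 with an estimated correlation) or 13 mitochondrially encoded genes (median 0.37, camera adjusted p = 0.00138; adjusted p = 0.716 with an estimated correlation). The last 2 calls were lost without wild-type 1 (adjusted p = 0.36 and 0.0906), without knockout 1 for the ribosomal list (0.44) and without knockout 3 for the mitochondrial list (0.508). In those fits the ribosomal median was 0.02 without wild-type 1 and 0.06 without knockout 1, and the mitochondrial median 0.25 without wild-type 1 and 0.14 without knockout 3. The ribosomal call was also lost with quantile normalization (median 0.13, adjusted p = 0.0552). Its median was 0.11 with array weights and 0.45 with Dbp as a covariate, and the mitochondrial median was 0.25 with GC and length correction and 0.60 with array weights. Without knockout 2 the medians were 0.33 and 0.70, and the ribosomal median was 0.30 without wild-type 3, with both lists still called. The mitochondrial median was 0.10 within the pair of knockout 2 and wild-type 1 and 0.55 between the other 4 libraries. Of 13 immediate early genes, Klf2 and Egr1 fell, and 3 adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.475 with an estimated correlation). That call was lost without wild-type 1 (adjusted p = 0.0808) or wild-type 3 (0.161), and without wild-type 1 and knockout 2 together (0.117). The median of -0.51 was -0.29 without wild-type 1, -0.27 without wild-type 3, -0.78 without wild-type 2, -0.89 without knockout 2 and -0.84 with Dbp as a covariate. With 1 library left out, Klf2 missed in 4 fits (without wild-type 2 or 3 or knockout 2 or 3, 0.0733 to 0.117). Egr1 missed without knockout 1 or 3 (0.0912 and 0.164) and passed without knockout 2. Without any one wild-type library, Egr1 was under the filter on low values and was not tested. Of 29 endoplasmic reticulum stress genes none passed by either adjustment (camera adjusted p = 0.0397; adjusted p = 0.716 with an estimated correlation). This call was lost under 11 of 25 alternatives, among them without wild-type 3 (adjusted p = 0.592), knockout 2 (0.423) and knockout 3 (0.0734). The median of -0.25 was -0.13 without wild-type 3, -0.16 without knockout 3 and -0.14 with Dbp as a covariate. In all, camera called 18 of 43 lists, 7 higher and 11 lower, and the other 9 splits of the same libraries called between 9 and 20 lists. The other 25 lists tested had adjusted p between 0.0663 and 0.984, and 7 lists had too few members to test.

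**Figure D2:**
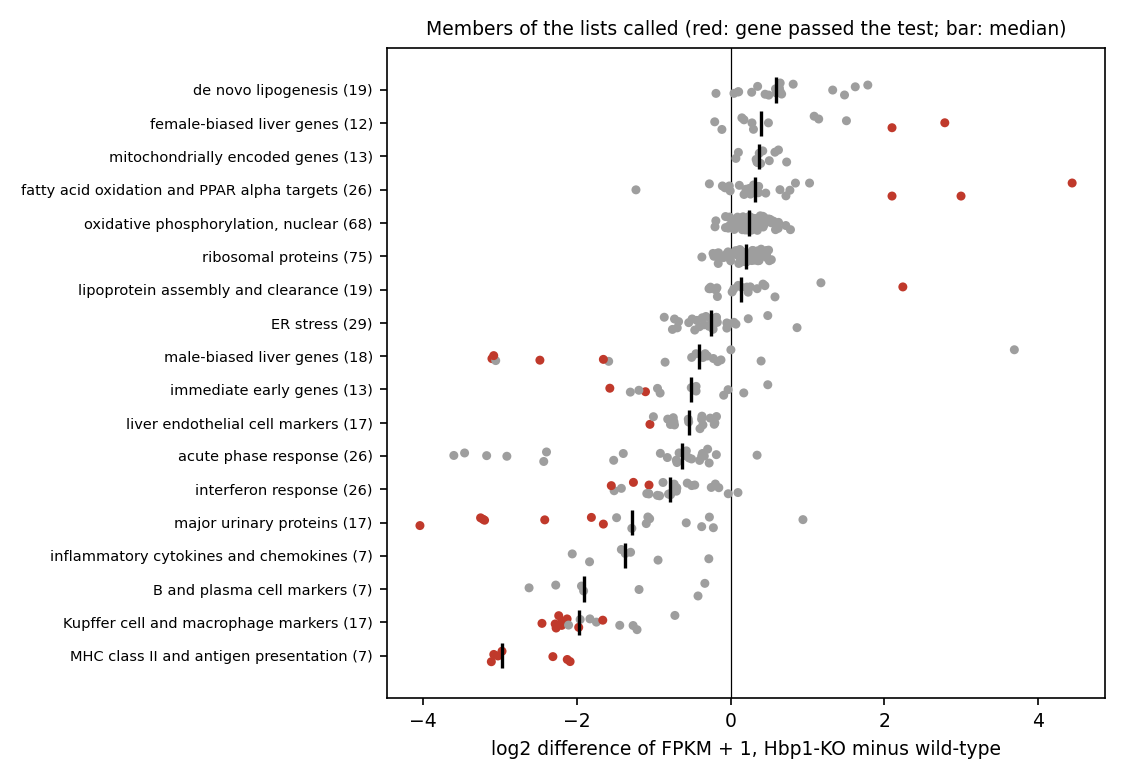
Log2 difference of FPKM + 1, knockout minus wild-type, of each tested member of the 18 called lists, with the number tested in brackets. Red points passed the single-gene test, grey points did not, and the bar is the list median, which runs from -2.98 (MHC class II) to 0.59 (de novo lipogenesis); the male-biased point at the far right is Serpina1e, which was not listed in wild-type 1 and was entered as 0.

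The libraries also differed within genotypes. Deviations from the gene mean correlated with GC content at 0.494 (Spearman) in wild-type 1 and between -0.338 and 0.084 in the others. Their correlations with transcript length ran from -0.283 in knockout 1 to 0.23 in knockout 2. The cause of these correlations was not tested. The first principal component held 38.4% of the variance and set wild-type 1 (-38.0) and knockout 2 (-29.2) apart from the other 4 libraries, and the second, with 31.4%, separated the genotypes. Between libraries, log2 ratios of low FPKM values piled up in one window only in 3 pairs, wild-type 1 with knockout 2 (6.47 times the even share), wild-type 2 with wild-type 3 (6.39) and knockout 1 with knockout 3 (6.83), against 2.13 to 3.15 in the other pairs. Of these 3 pairs, 2 lie within a genotype. For those 4 libraries, this pairing and genotype cannot be told apart. All 138 genes past the threshold differed in the same direction between knockout 2 and wild-type 1 and between the other 4 libraries, which follows from their groups not overlapping.

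**Figure D3:**
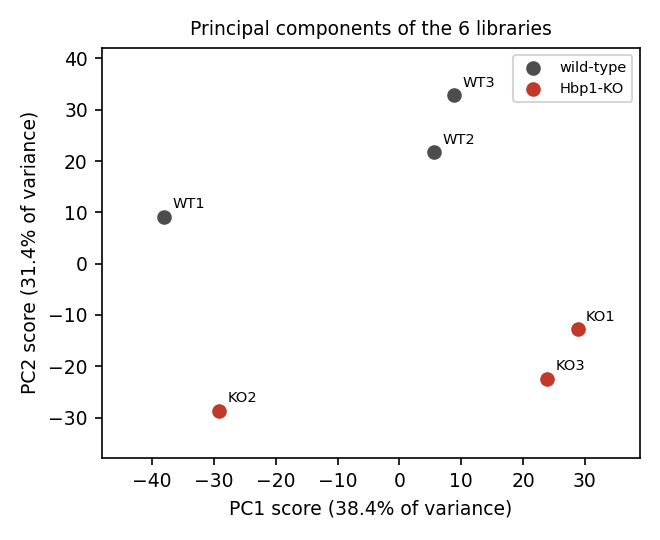
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), with the percent of variance on each axis, wild-type in grey and knockout in red. Wild-type 1 and knockout 2 have negative scores on the first component (-38.0 and -29.2), and the genotypes lie apart on the second.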

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

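The fits with only genes listed in all 6 files, without wild-type 1 and knockout 2, with a term for those 2 libraries, with GC and length correction, with Dbp as a covariate and with copies summed were chosen after seeing the data. Hbp1 passed under all 25 alternatives (-2.71 to -2.26, adjusted p from 6.02e-05 to 0.0391; -2.50 to -2.26 with 1 library left out). Igfbp1 was lower in each (adjusted p from 0.000648 to 0.35) and passed in 6: array weights (-4.03), replicate block (-3.25), without wild-type 1 (-4.13), without wild-type 1 and knockout 2 (-4.65), the term for them (-3.25) and Dbp as a covariate (-3.09). With 1 library left out it ranged from -4.13 to -2.68.

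The 138 genes became 8 with no filter (more genes tested), 54 at a mean FPKM of at least 5 (fewer), 83 with median-of-ratios scaling and 86 with quantile normalization. They became 867 with array weights (0.241 for knockout 2, 0.351 for wild-type 1) and 24 with the replicate block. The count was 366 with the term for wild-type 1 and knockout 2, and 208 at adjusted p under 0.1. Apart from the looser threshold, the causes of these changes were not tested, the number of genes tested among them. With 1 library left out, 28 to 122 genes passed, 28 without knockout 3, 39 without wild-type 2, 40 without wild-type 3 and 42 without knockout 2. Same-numbered libraries did not all deviate together (-0.30, -0.354 and 0.263). This does not exclude a pairing by number, since wild-type 1 and knockout 2 stand apart from the other libraries. Of 38 named genes past the threshold, 17 passed in every fit with 1 library left out that tested them. In each such fit 6 to 16 were lost. Acot3, Slc39a5 and Vcp-rs, among the 17, were under the filter on low values without any one knockout library, and were not tested there. With no filter 34 of the 38 were lost and with the replicate block 23, and no other setting with all 6 libraries lost more than 10 of those it tested. Vcp-rs reversed with copies summed (-0.51 against 3.07).

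The 18 lists became 0 with an estimated correlation and 0 with directional fry (11 in its mixed test), and 14 to 23 with 1 library left out; 10 were called in all 25 refits. The cholesterol synthesis list, not called (-0.07), ranged from -0.52 to 0.42 with 1 library left out, reversed and called without knockout 3 (the cause was not tested). Count tests were planned but not run, since whole reads could not be recovered, so what depth limits is unknown.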

Other observations

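Apart from the splits of the libraries and the tests of the clock list, all tests in this part were chosen after the result was seen. Genes of the circadian clock differed between libraries of the same genotype. Dbp, a clock output transcription factor, had an FPKM of 57.3 in wild-type 1 and of 2.04 and 0.712 in wild-type 2 and 3, and of 2.02 in knockout 1 and 173 and 157 in knockout 2 and 3. Arntl, the core activator that peaks in the opposite phase, was at 0.686 in wild-type 1, 4.81 and 5.07 in wild-type 2 and 3, 3.40 in knockout 1, and 0.399 and 0.135 in knockout 2 and 3. The clock list was not called (camera adjusted p = 0.164), and 0 of 15 members passed over all genes and 1 adjusted over the list alone. Metallothionein Mt1 was at 1706 in wild-type 3, 816 in knockout 1 and 404 in knockout 3, and between 60.7 and 98.0 in the others. Scd1, stearoyl-CoA desaturase, was at 2669 in knockout 2 and between 281 and 535 in the others.

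With 10 splits of the 6 libraries, 3 against 3, no share under 0.05 can be had. The real split gave 138 genes and the highest other 4, so that 1 of the 10 splits, the real one, gave as many. It gave 18 lists, and 3 of the 10 splits, the real one included, gave at least as many. The highest other, with 20 lists, was the split that set wild-type 1, knockout 2 and knockout 3 against the rest.

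Macrophage and MHC class II genes were lower in the knockout. Less blood in the samples is argued against by erythroid markers, whose median lay 1.55 above that of macrophage markers. An exact permutation test of the difference of means gave adjusted p = 2.78e-06 over 3 comparisons. It permuted genes, which are not independent replicates. An equal fall of all cells other than hepatocytes is argued against by stellate and endothelial markers, whose medians lay 1.87 and 1.43 above. The same tests of means gave adjusted p = 2.78e-06 and 1e-05, from the smallest p that each test can give. Still, 7 of 8 stellate and 17 of 17 endothelial markers were below 0, so a smaller fall of these cells stays open. B and plasma cell markers (median -1.91) and the 4 T and NK cell genes (-1.29) lay nearer to macrophage markers. Within the pair of knockout 2 and wild-type 1, however, the B and plasma cell median was 0.68 and the macrophage median -2.02. Between the other 4 libraries these medians were -3.10 and -1.93. A fall shared by immune cells was not tested. A library preparation shared by pairs, inferred only from ratios of low FPKM values, stays open. The median difference of -2.03 between knockout 2 and wild-type 1 rests on 1 library of each genotype. Fewer macrophages, less expression per macrophage and the genotype itself may each account for the pattern and were not separated.

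Where male-biased genes were lower and female-biased genes higher, a library of the other sex is argued against by Y-linked FPKM, whose lowest knockout sum was 116.8% of the wild-type mean; the lowest library of all was wild-type 1, at 58.9%. A linear trend with Dbp did not account for the male-biased fall, whose median was -0.67 with Dbp as a covariate. Camera at the preset correlation still called the list (adjusted p = 2.37e-08). Without Dbp, the same setting called 9 to 20 lists in splits that mixed the genotypes. The kept call therefore cannot tell genotype from variation that genes share between libraries. Libraries alike in Dbp still differed in a lipid gene (knockout 2 and 3, Dbp 173 and 157, Fasn 251 and 62.0). Dbp is thus a partial stand-in, and collection time and feeding stay open. Reads shared between copies are argued against for male-biased genes, of which all 4 passed with copies summed (Cyp7b1 and Nat8 have none). Shared reads stay open for major urinary proteins, whose summed change was -1.42 ± 0.376 (adjusted p = 0.13, against -4.04 ± 0.284 for Mup7 alone). The sum moved less and had a larger standard error. The genotype stays open, not tested apart from a library preparation shared by pairs, which is inferred only from ratios of low FPKM values.

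Of the 37 higher genes, 9 have a near-identical copy. They were sorted by whether they passed with copies summed (6 did and 3 did not), so the sorting itself is no test. Apoc2, Cyp4a10, Mid1ip1 and 3 Tmem254 genes passed, in 4 separate families (the Tmem254 genes share 1 sum). For each of these families taken alone, the rise of the sum argues against reads moved from the copy. For Gm13305, Gm10320 and Vcp-rs, which gained 10.9, 13.5 and 12.0 FPKM, reads moved from the copy stay open. Their copies changed by -0.91, -1.92 and -35.7 FPKM (SE 7.26, 23.9 and 10.9). For Gm13305 and Gm10320 this lay 1.38 and 0.49 standard errors above a fall as large as the gain. For Vcp-rs it lay at -2.17 standard errors, below such a fall. The standard error for Gm10320 exceeded its gain, so there the comparison could not decide. None of the 3 passed with copies summed (log2 differences 0.55, 0.07 and -0.51, limma adjusted p = 0.704, 0.98 and 0.708). For these 9 genes, a chromosome segment carried along with the knockout around Hbp1 is argued against, since 0 of them lie within 20 Mb of Hbp1. Sequence differences elsewhere in the genome were not tested.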
